A study of Mus musculus with 4 samples.

How the data were processed

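RNA was measured in granulocyte monocyte progenitors (GMP) and in cells labelled MDP, sorted from wild-type and Trib1-/- mice, with 1 Affymetrix array per group and 4 arrays in all. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared with the NuGEN Ovation system, which amplifies small amounts of RNA. Amplification of this kind can widen the spread of weakly expressed genes. Per the submitters' processing notes the authors used RMA, which corrects the background, makes the distributions of the arrays alike and summarises the probes of each probe set. Its version is not given in the sources used here, nor are the sort gates, the number of animals per array or the array batches. The deposited values are taken as log2 values. That scale is inferred from their range, from 0.14 to 14.5, and is not stated in the file. The medians of the arrays (3.27, 3.29, 3.31 and 3.27) show values that are not centred on 0, and the columns hold single arrays, so no direction of a ratio is in question. RMA makes the arrays' distributions alike, so a difference in the total amount of RNA per cell cannot be seen in these values, and a loss of many transcripts on 1 array can appear as a relative gain of others. RMA values of weak probe sets lie near the background, so folds of weakly expressed genes are uncertain and can be too small or too large in size. No column of another sample was present, and the genome build is not given in the sources used here, so no coordinates are printed.

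Of the 45101 probe sets, 64 were control probe sets and were left out of the gene counts. In the platform annotation 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not listed. Only those with 1 symbol were named. The gene identifiers of 34741 were found in a reference gene table, which changed 0 symbols. Genes without a usable probe set, such as Cebpe and Ly6c1, are not analysed here. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 18193 genes. A gene was used where the highest of its 4 values reached the floor, the median of all values (3.29), which left 11653 genes. Other probe sets of named genes were compared, and where they went the other way or differed widely this is stated for the main genes named.

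The differences formed were 4: knockout minus wild type in GMP and in MDP, and MDP minus GMP in wild type and in the knockout. With 1 array per group there is no estimate of the spread between animals, sorts or arrays within a group, so no test was made. A residual over the 4 arrays would mix that spread with a different genotype effect in the 2 progenitors, and was not used. Genes were counted by a fixed size, a log2 difference of at least 1 (2-fold). Before the data were examined, 24 gene lists and the rule for named genes were fixed, along with all alternatives not marked otherwise. A list needed at least 5 members above the floor to be scored, and 22 lists had them. The median difference of each list was set against 10000 random lists of the same size, drawn with seed 1 from 20 bins of mean expression, as a description of these arrays and not as a test. Genes of a list are regulated together, so medians outside the central 95% are more frequent than for random genes. Over 88 medians, 35 lay outside it. The rule named Trib1, 14 regulators and receptors where measured (12 were), the 8 largest genes in each direction whose probe sets above the floor had 1 direction, up to 4 members of each list, and the 8 largest genes shared by both progenitors. Names of predicted genes were left out of the largest genes. Other genes are said to have been chosen after their values were seen.

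Chosen after the data were seen were 3 lists (resident macrophage genes, other mature macrophage genes, and the basophil, mast cell and eosinophil genes together), families grouped by symbol, the values with the floor in place of anything below it, and the counts without those families. The tolerances that call a list median, a gene or a correlation moved (the SD between probe sets, and 0.1 for the correlation) were also set then. The members of the list of other mature macrophage genes were written down before their values were looked at.

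The alternatives were no floor, a floor at the 75th percentile of all values, the mean of a gene's probe sets, leaving out probe sets that can hybridise to several transcripts (by suffix), cyclic loess of the 4 arrays (3 iterations), centring each array on the median above the floor, adding 32 to the linear value before log2, and size rules of 1.5-fold and 4-fold. The calculation was tested on simulated data for the MDP genotypes with 11653 genes and normal noise of SD 0.384, the same for every gene. That SD came from the interquartile range of the observed MDP difference over genes. Of 200 genes made to differ, 92.0% of those set to a log2 difference of 1.5 and 100% of those set to 2.0 were counted in the right direction. Of the others 0.98% were counted, a share that follows from the SD chosen and is no error rate of these arrays. Lists of 10 genes lay outside the central 95% in 4.0% of cases with no shift, in 88.0% with a shift of -0.5 and in 100% with -1.0. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for the loess.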

Results

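Gene expression was measured in 2 sorted mouse blood progenitors, each from wild-type and Trib1-/- animals of a mixed C57BL6J/129SV background. Granulocyte monocyte progenitors (GMP) give rise to granulocytes and monocytes, and MDP is the label of the other population, whose cell type is given as macrophage dendritic cell. MDP is the usual name of the monocyte (or macrophage) and dendritic cell progenitor. Total RNA from unstimulated cells was amplified, labelled with biotin and hybridised to an Affymetrix mouse array. The series holds 4 arrays, 1 for each combination of cell type and genotype, so no difference below has a replicate check and no test or p-value is given. Each array held 45101 probe sets, and the array medians lay at 3.27 (wild-type GMP), 3.29 (Trib1-/- GMP), 3.31 (wild-type MDP) and 3.27 (Trib1-/- MDP) on the log2 scale. Of 18193 named genes, 11653 reached the floor of 3.29, the median of all values, on at least 1 array. All differences are log2 differences of RMA values, and a gene was counted where the difference was at least 1 in size, that is at least 2-fold. The number of arrays limits the precision. The spread that could be measured was that between probe sets of 1 gene on the same arrays. Its SD was 0.372 for the GMP genotypes and 0.383 for the MDP genotypes, over 4922 genes with several probe sets above the floor, and it leaves out the spread between animals, sorts and arrays.

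Trib1 encodes a pseudokinase that brings the C/EBP transcription factors to the COP1 ubiquitin ligase. Its 2 probe sets did not separate the genotypes. The first read 4.85 in wild-type GMP, 5.19 in Trib1-/- GMP, 5.13 in wild-type MDP and 4.71 in Trib1-/- MDP. The second read 4.95, 5.10, 5.99 and 5.56 in the same order. The signal was thus higher by 0.34 and 0.15 in the GMP array labelled Trib1-/- and lower by 0.41 and 0.43 in the MDP array so labelled. The deleted part of the gene and the target positions of the probes are not given in the sources used here, so Trib1 does not check the labels. Knockout below means the array labelled Trib1-/-, and each direction drawn from genotype rests on those labels.

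The first question was how loss of Trib1 altered the expression profile of GMP. The clearest group was that of basophil and mast cell genes, all 8 of whose measured members were lower in knockout GMP, 4 of them at least 2-fold. Gzmb, which encodes granzyme B, was 10.3-fold lower, Cpa3, the mast cell carboxypeptidase, 5.2-fold, the basophil protease gene Mcpt8 2.9-fold, and Hdc, which encodes the enzyme that makes histamine, 2.2-fold. The list's median difference was -1.05, below the central 95% of 10000 random lists matched on expression, whose lower limit was -0.45. Fcer1a and Ms4a2, chains of the IgE receptor, differed by -0.95 and -0.83, and Gata2 by -0.91. Of the eosinophil genes only 4 were above the floor, too few to score. Among them Siglecf was 2.9-fold and Prg2, which encodes major basic protein, 2.3-fold lower, while Epx (-0.37) and Il5ra (-0.02) differed by less than 2-fold. The knockout value of Gzmb lay below the floor, and with values below the floor raised to it the Gzmb difference was -1.71 in place of -3.37. The knockout value of Siglecf (3.11) was also below the floor. Cpa3 was above the floor on both GMP arrays.

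In total 56 genes were at least 2-fold higher and 368 at least 2-fold lower in knockout GMP, so 86.8% of the 424 genes apart were lower. Beside the basophil genes, the largest lower genes included several of mitochondria: Higd2a (-2.002), Atp5e, a subunit of ATP synthase (-1.94), and Timm13, of the import machinery (-1.89, or -0.94 with values below the floor raised to it). Aaas, a nuclear pore protein, differed by -2.05 (-1.76 once raised). Tmem107 (-2.14) barely reached the floor and was at -0.005 once raised, and Lbh (-1.83, or -1.15 once raised) had a second probe set at -0.01. Ctse, the cathepsin E gene, had the largest lower value (-3.55), but its second probe set went the other way (0.60), so it is given only as a value chosen after it was seen. The largest higher genes were Plcxd2 (2.59), the sodium chloride transporter gene Slc12a3 (1.95), Pik3r3 (1.81), Strip2 (1.77), Mfhas1 (1.76) and Tshb (1.73), together with the inducible heat shock genes Hspa1a (1.84, or 0.23 with the low wild-type value raised to the floor) and Hspa1b. All 3 probe sets of Hspa1b were higher, by 1.63 or more. Wild-type values of Plcxd2, Pik3r3 and Strip2 also lay below the floor, and with values raised to it the differences were 1.84, 0.77 and 1.42. The second probe set of Plcxd2 read 0.47.

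Further lists had medians below the random range in knockout GMP. Primary granule and early granulocyte genes had a median of -0.55, with 10 of 11 below 0 and none at least 2-fold lower. Their largest differences were Nkg7 (-0.99), Cst7 (-0.86), Hp (-0.79) and Gfi1 (-0.66). S phase genes had a median of -0.38, with Ccne2 at -1.07 (-0.70 with its low knockout value raised to the floor) and E2f1 at -0.92, though 1 probe set of E2f1 went the other way. Mitosis genes had a median of -0.41, with 4 of 23 at least 2-fold lower: Ube2c (-1.45), Birc5 (-1.12), Cdk1 (-1.11) and Cenpf (-1.11, other probe set -0.21). Cytosolic ribosomal protein genes had a median of -0.62, with 4 of 20 at least 2-fold lower, among them Rps14 (-1.22) and Rpl8 (-1.22). Stem and early progenitor genes had a median of -0.32, with Cd48 at -1.16, unfolded protein response genes -0.35, with Sdf2l1 at -0.97, and immediate early and stress genes -0.38. In the last of these Hspa1a and Hspa1b were higher while Dusp1 (-1.20), Zfp36 (-1.14) and Ier3 (-1.10) were lower. The mitosis median moved inside the random range when a gene's probe sets were averaged, and those of the stem, unfolded protein and immediate early lists did so under 3 alternatives each. Genes outside these lists were lower too. Mitochondrial ribosome, NADH dehydrogenase and proteasome genes, 151 genes grouped by name after the data were seen, had a median of -0.63 in knockout against wild-type GMP, and the hybridisation controls BioB and BioC read 0.37 higher on the knockout array.

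The other scored lists lay inside the random range in GMP. Among them, monocyte and macrophage genes had a median of -0.02 with none of 26 at least 2-fold apart, late neutrophil genes -0.06, dendritic cell genes -0.18 and M2-like macrophage genes -0.09. The list of Trib, COP1 and C/EBP genes had a median of -0.19, with Trib2 at 1.18 (0.38 with its low wild-type value raised to the floor) and the ligase scaffold gene Cul4a lower (-1.10). Of the regulators, Irf8 differed by -0.70, Cebpa by -0.64, Gfi1 by -0.66, Kit by -0.63, Spi1 by -0.37, Cd34 by -0.32 and Flt3 by -0.29. Klf4 (0.31), Csf3r (0.29), Cebpb (0.05), Cx3cr1 (-0.27) and Csf1r (0.01) were also less than 2-fold apart, and the other probe sets of Csf1r read as low as -0.55. Of the genes at least 2-fold apart that had several probe sets above the floor, 80 of 120 (66.7%) had all of them in 1 direction. With 32 added to the linear values, 1 gene was 2-fold higher and 15 were lower. Cpa3 was the only member of the basophil and mast cell list among the 15, and Gzmb was not. Others were the ribosomal protein genes Rps14, Rps15, Rps9 and Rplp2, and Atp5e, Pfn1 and Dusp1.

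**Figure D1:**
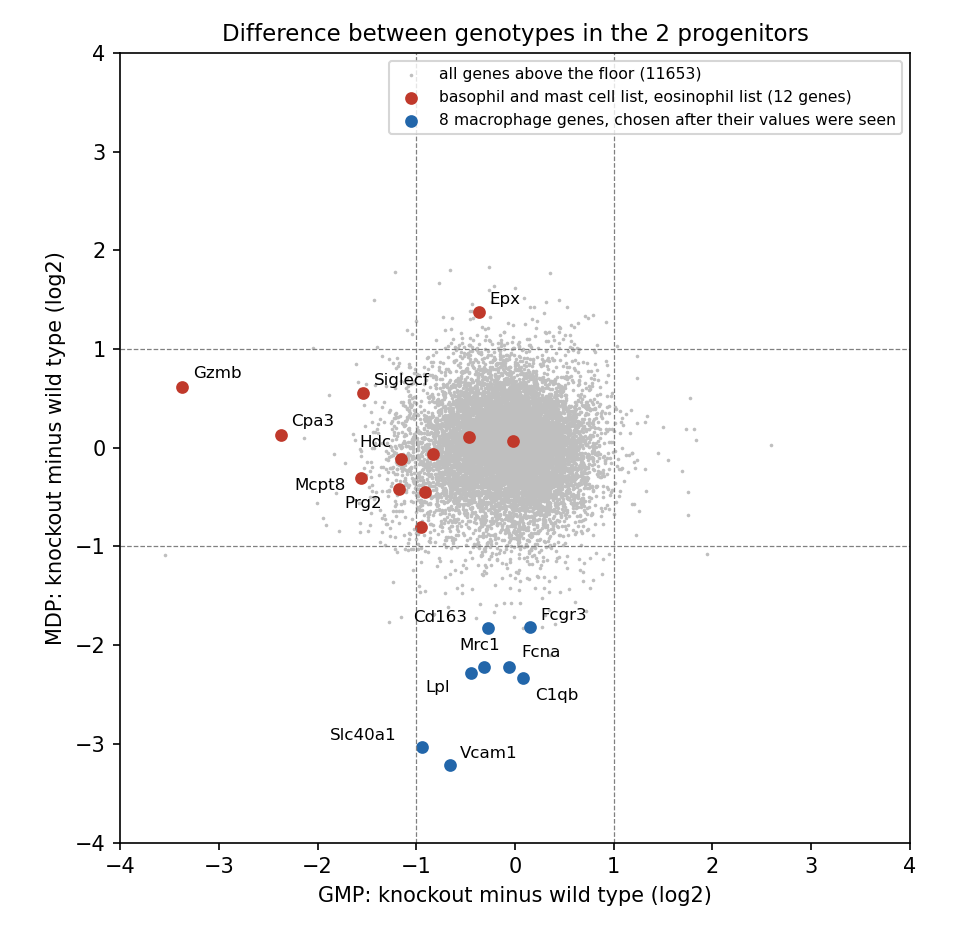
Difference between genotypes (knockout minus wild type, log2 RMA value) in GMP on the horizontal axis and in MDP on the vertical axis, 1 point per gene above the floor (11653 genes, 1 array per group), with dashed lines at 2-fold. Red points are the 12 measured genes of the basophil and mast cell list and the eosinophil list, with Gzmb (-3.37) and Cpa3 (-2.37) far to the left; blue points are 8 macrophage genes chosen after their values were seen, with Vcam1 (-3.21) and Slc40a1 (-3.03) lowest.

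In MDP the genes with the largest differences were of another kind. Several of the largest lower genes, grouped after they were seen, are genes of macrophages: the adhesion molecule gene Vcam1 by 9.3-fold, Slc40a1, which encodes the iron exporter ferroportin, by 8.2-fold, the complement gene C1qb by 5.0-fold, Lpl, the lipoprotein lipase gene, by 4.9-fold, Mrc1, the mannose receptor gene, by 4.7-fold, and Fcna, which encodes ficolin A, by 4.7-fold. Cd163, the haemoglobin scavenger receptor gene, was 3.5-fold lower and the Fc receptor gene Fcgr3 3.5-fold lower. Unlike the other macrophage genes named here, which were highest in wild-type MDP, Fcgr3 read higher in GMP. It was at 6.58 in wild-type GMP and 6.74 in knockout GMP, against 4.735 in wild-type MDP. The second probe set of Vcam1 read -1.46. Lgi1 (-2.10) and Snhg7 (-1.82) completed the 8 largest. Knockout values of C1qb, Lpl, Fcna, Fcgr3 and Snhg7 lay below the floor. With such values raised to it the differences of Vcam1, Slc40a1 and Mrc1 stood as they were, Lpl was at -1.66, Fcgr3 at -1.45, C1qb at -0.98, Snhg7 at -0.73 and Fcna at -0.13.

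A list of 22 resident macrophage genes, drawn up after these values were seen and containing them, had 16 members above the floor. Of these, 11 were at least 2-fold lower in knockout MDP, among them Hmox1 (-1.44), Spic (-1.26) and Mertk (-1.01), and the median was -1.56, or -0.995 with values below the floor raised to it. The knockout value of Hmox1 was below the floor. In GMP the list had a median of -0.03 between genotypes, but only 7 members were above the floor on both GMP arrays, so this is no contrast to MDP. The lists fixed beforehand showed less. M2-like macrophage genes had a median of -0.29, just inside the random range (lower limit -0.31), with 2 of 12 at least 2-fold lower, Mrc1 and Cd163, and Arg1 at 0.80 (0.45 once raised). Monocyte and macrophage genes had a median of -0.02, with 2 of 26 at least 2-fold lower, Fcgr3 (-1.81) and Slpi (-1.24). The regulators of the monocyte lineage were less than 2-fold apart between genotypes, with Irf8 at -0.04 (other probe set 0.30), Csf1r at -0.01, Klf4 at 0.02 (other probe set -0.40) and Cebpa at 0.02, while Flt3 read 0.65, Cd34 0.34, Kit 0.26, Csf3r -0.53, Gfi1 -0.44, Spi1 -0.44, Cebpb -0.30 and Cx3cr1 -0.31. Kit and Gfi1 lay below the floor on both MDP arrays, and Csf3r was at -0.06 with its low knockout value raised to the floor.

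In total 128 genes were at least 2-fold higher and 178 at least 2-fold lower in knockout MDP (58.2% lower). The largest higher genes were Cad, which encodes an enzyme of pyrimidine synthesis (1.83), Tmem201 (1.80), Gdpd3 (1.78), Samd9l (1.77), Rhot1 (1.64), Pcp2 (1.62), Wfs1 (1.59) and Myzap (1.502). Of these only Rhot1 had a wild-type MDP value above the floor. With values raised to it the differences were 1.30 for Cad, 1.23 for Tmem201, 1.18 for Samd9l, 1.38 for Pcp2, 0.40 for Gdpd3, 0.30 for Wfs1 and 0.15 for Myzap, and 1 probe set of Tmem201 read 0.01 and 1 of Rhot1 0.21. Interferon response genes had a median of 0.32, above the random range, with 8 of 10 above 0 and none at least 2-fold apart. Oas1a read 0.65 (0.20 once raised) and Ifih1 -0.59, and the median moved inside the range when values below the floor were raised to it. Immediate early and stress genes had a median of -0.24, below the range, with Ier2 at -0.67, Dusp1 at -0.64 and Nr4a1 at 0.61. All 20 measured cytosolic ribosomal protein genes were below 0 (median -0.32), none at least 2-fold, with Rps14 at -0.91 and Rps3 at -0.82. Lists inside the range held single genes at least 2-fold apart: Car2 (-1.69) and Tal1 (-1.18) of the erythroid list, Slamf1 (-1.17, with a probe set at -0.22) of the stem cell list and Icam1 (1.07) of the NF-kB list. Basophil and mast cell genes had a median of -0.09 in MDP, where most lay below the floor. Of the genes at least 2-fold apart with several probe sets above the floor, 33 of 63 (52.4%) had all of them in 1 direction. With 32 added to the linear values, 0 genes were 2-fold higher and 3 were lower (100%): Vcam1, Slc40a1 and Mrc1.

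**Figure D2:**
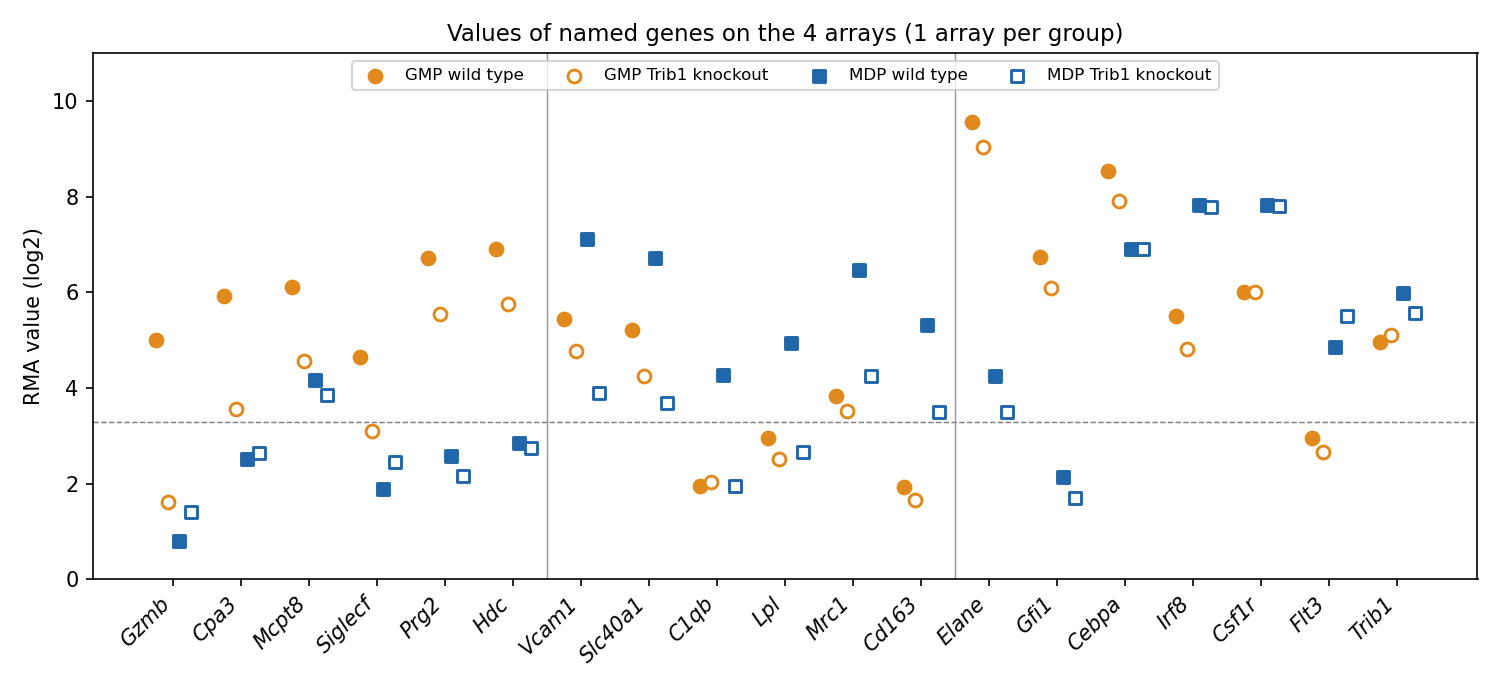
RMA values (log2) of 19 genes on the 4 arrays, 1 array per group; circles are GMP and squares MDP, filled for wild type and open for the Trib1 knockout, and the dashed line is the floor of 3.29. Gzmb to Hdc are basophil, mast cell and eosinophil genes, highest in wild-type GMP; Vcam1 to Cd163 are macrophage genes, highest in wild-type MDP; the rest are Elane, 5 regulators or receptors and Trib1.

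Across all genes, the differences between genotypes in the 2 progenitors were uncorrelated, although some lists were low in both. Across the 11653 genes the GMP and MDP differences, which have no array in common, had a Pearson correlation of -0.0065 and a Spearman correlation of -0.0297, over genes that are not independent replicates. Noise of single arrays would also give a correlation near 0, so these values do not show that the genotype acted differently in GMP and MDP. Cytosolic ribosomal protein genes (medians -0.62 and -0.32) and immediate early and stress genes (-0.38 and -0.24) lay below the random range in both. At least 2-fold in both, 11 genes were lower where independent lists of these sizes would share 5.62, and 1 was higher (5730419F03Rik) where they would share 0.62. Those lower in both included Bsg, a transmembrane chaperone of lactate transporters (-1.15 in GMP and -1.72 in MDP), Ndufs7, a subunit of NADH dehydrogenase (-1.27 and -1.77), the RNA exosome gene Exosc5 (-1.24 and -1.36), Cd27 (-1.04 and -1.24), Cenpx, Cyb5r1, Fxyd5 and Eapp. Knockout MDP values of Bsg, Exosc5, Cd27, Cenpx and Cyb5r1 lay below the floor, and raised to it their MDP differences were -0.42, -0.85, -0.36, -0.97 and -0.46, so these are not shared at 2-fold. That of Ndufs7 was at -1.68, and Eapp and Fxyd5 were above the floor on all arrays. The count in both directions, 12 genes, was 4 with values below the floor raised to it and 0 with 32 added to the linear values. Genes within 10 Mb of Trib1, where a mixed background can leave DNA of the other strain, did not stand apart: the median size of the difference over 47 genes was 0.251 in GMP (percentile 27.9 of matched random lists) and 0.274 in MDP (percentile 72.2). In each, 1 of them was at least 2-fold apart, Med30 in GMP and 9130401M01Rik in MDP.

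**Figure D3:**
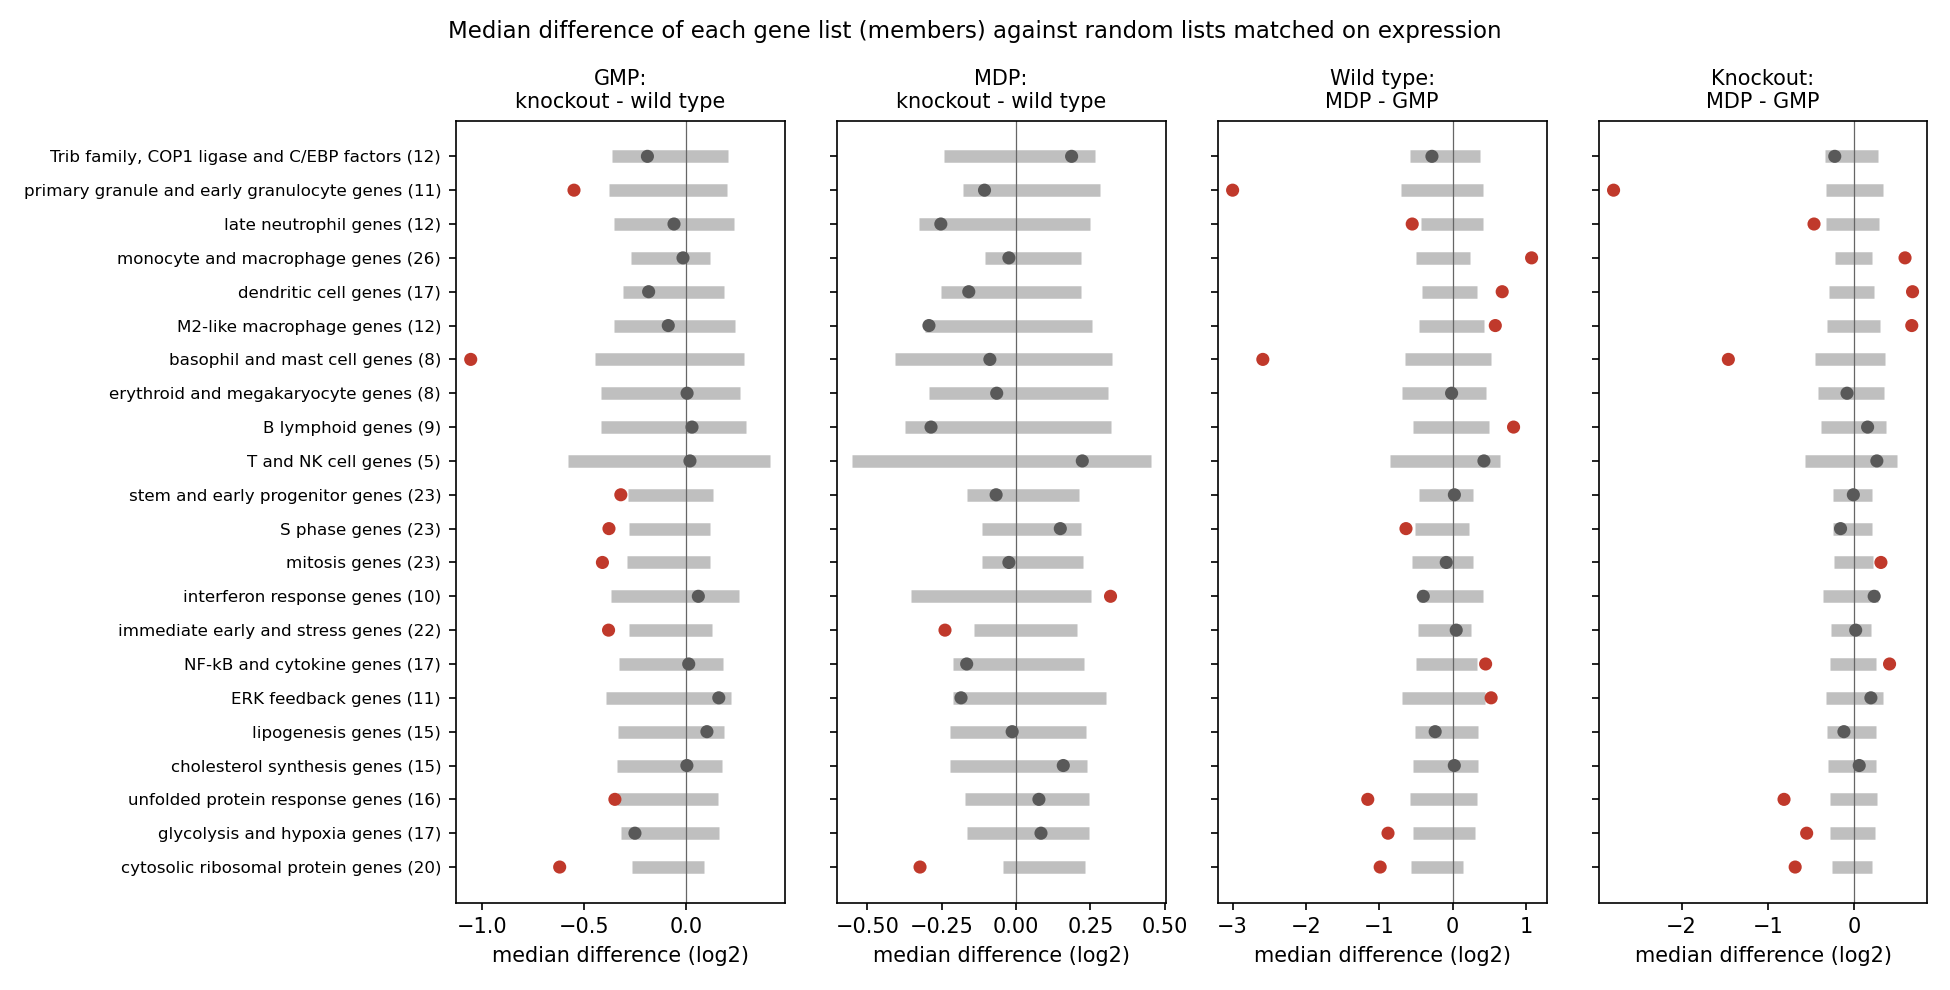
Median log2 difference of each of 22 gene lists (number of members above the floor in brackets) in the 4 comparisons, with the central 95% of 10000 random lists matched on expression as grey bars; red points lie outside it, and the horizontal scales differ between panels. Basophil and mast cell genes lie lowest in GMP between genotypes (-1.05), and primary granule genes lie lowest in both MDP against GMP panels (-3.00 and -2.79).

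The contrast between the 2 progenitors was larger than that between genotypes, and more so in wild type than in the knockout. Genes at least 2-fold apart were 1930 in wild type and 795 in the knockout, against 424 between the GMP genotypes and 306 between the MDP genotypes. The larger count in wild type rests on the single wild-type GMP array. That array correlated less with wild-type MDP (0.948) and knockout MDP (0.9497) than knockout GMP did (0.9645 and 0.967). A feature of that array and an effect of genotype cannot be told apart here. In wild type, 485 genes were at least 2-fold higher and 1445 at least 2-fold lower in MDP than in GMP. All 11 measured primary granule and early granulocyte genes were at least 2-fold lower in MDP (median -3.00), with Ms4a3 70.5-fold, the neutrophil elastase gene Elane 40.1-fold, Nkg7 24.5-fold and the repressor gene Gfi1 24.2-fold lower. All 8 basophil and mast cell genes were also at least 2-fold lower (median -2.59), among them Gzmb (-4.20) and Cpa3 (-3.41), and the eosinophil gene Prg2 read -4.14. Prom1 (-4.76), Kit (-3.58), Cebpa (-1.64), Cd34 (-1.35) and Csf3r (-0.91) were lower as well. MDP values of Gzmb, Cpa3, Prg2, Gfi1, Prom1 and Kit lay below the floor, so their folds are uncertain. Raised to it, Gzmb was at -1.71, Prg2 at -3.44, Gfi1 at -3.45 and Prom1 at -3.67. Monocyte and macrophage genes had a median of 1.08, with 15 of 26 at least 2-fold higher and 2 lower. Ahnak (3.35, other probe set 0.65), Mpeg1 (3.02), Ctss (2.44) and Irf8 (2.31) led them, with Csf1r at 1.82 and Klf4 at 1.02, while Spi1 (-0.40), Cebpb (0.09) and Cx3cr1 (0.34) were less than 2-fold apart. Dendritic cell genes had a median of 0.68, with the cytokine receptor gene Flt3 (1.90), Spib (1.38) and Tcf4 (1.33, with a probe set at 0.39) at least 2-fold higher. M2-like macrophage genes had a median of 0.58, led by Cd163 (3.39, or 2.03 with its low GMP value raised to the floor) and Mrc1 (2.64). The resident macrophage list, of which these are members, had a median of 1.62 in wild type and 0.08 in the knockout, which follows from its choice for high values on the wild-type MDP array.

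B lymphoid and signalling genes also differed in wild type. B lymphoid genes had a median of 0.83, with Dntt, the terminal transferase gene, higher (2.97), NF-kB and cytokine genes 0.45, with Cd83 at 2.56, and ERK feedback genes 0.53, with Ccnd1 at 2.24 (lowest probe set 0.48). Unfolded protein response genes were lower (median -1.16, 11 of 16 at least 2-fold), led by Sdf2l1 (-2.99, or -2.49 once raised), Manf (-2.42) and the transcription factor gene Xbp1 (-1.83). Glycolysis and hypoxia genes had a median of -0.88, with Egln3 at -2.19 and Aldoa at -1.70 (a probe set at -0.32), S phase genes -0.64, late neutrophil genes -0.55 and cytosolic ribosomal protein genes -0.99. Beside these lower lists, the 151 mitochondrial and proteasome genes had a median of -0.945, and BioB and BioC read 0.66 higher on the wild-type MDP array. Cep85 had the largest higher value (4.37), but its other probe set read 0.04, and second probe sets of Plcxd2 (3.09) and Dntt read 0.16 and 0.57. With low GMP values raised to the floor, Plcxd2 was at 2.34, Dntt at 1.98, Itgb7 at 2.32 and Strip2 at 2.40. Itgb7 (2.88) and Strip2 (2.75) rested on 1 probe set each. With 32 added to the linear values, 48 genes were higher and 320 lower, 87.0% lower in place of 74.9%. The late neutrophil median moved inside the random range under 4 alternatives, and those of the B lymphoid, ERK feedback and S phase lists under 1 each.

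In the knockout, 320 genes were at least 2-fold higher and 475 lower in MDP than in GMP. Most of the lists outside the random range in wild type were so again, but B lymphoid (0.15), ERK feedback (0.19) and S phase genes (-0.16) lay inside it. All 11 primary granule genes were at least 2-fold lower (median -2.79), with Elane 46.2-fold, Ms4a3 34.7-fold and Gfi1 20.8-fold lower, and Prom1 was 67.4-fold lower. Knockout MDP values of Prom1 and Gfi1 lay below the floor, and raised to it the log2 differences were -3.81 in place of -6.07 and -2.79 in place of -4.38. Monocyte and macrophage genes had a median of 0.59, with 11 of 26 at least 2-fold higher, among them Mpeg1 (3.07) and Irf8 (2.96), and with Fcgr3 at -3.81. Dendritic cell genes had a median of 0.67, with Flt3 (2.84) and Spib (1.43) higher, M2-like macrophage genes 0.66 and NF-kB and cytokine genes 0.41. Ctsh (3.06), Ptpro (3.14) and Pdzd4 (3.26) were among the largest higher genes, Sgms2 (-4.44) and Mgam (-3.96) among the largest lower. With low values raised to the floor, Ptpro was at 2.31, Flt3 at 2.22, Spib at 1.13, Sgms2 at -2.34, Mgam at -3.71 and Fcgr3 at -3.45. Basophil and mast cell genes had a median of -1.46, with 5 of 8 at least 2-fold lower. Unfolded protein response genes (-0.82), glycolysis and hypoxia genes (-0.55), cytosolic ribosomal protein genes (-0.69) and late neutrophil genes (-0.47, lost under 3 alternatives) were again below the random range, and mitosis genes (0.31) were above it, with Cenpf at 1.42. Kit (-2.69, or -2.10 once raised), Csf3r (-1.73, or -1.26), Csf1r (1.80), Cebpa (-0.99), Klf4 (0.73), Cd34 (-0.69), Spi1 (-0.47), Cx3cr1 (0.30) and Cebpb (-0.26) had the same sign as in wild type apart from Cebpb.

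The MDP against GMP differences of the 2 genotypes, which have no array in common, had a Pearson correlation of 0.597 and a Spearman correlation of 0.519 across the 11653 genes, which are not independent replicates. At least 2-fold higher in MDP in both genotypes were 115 genes, where independent lists would share 13.3, and 332 were lower in both, where they would share 58.9. T and NK cell, erythroid and megakaryocyte, lipogenesis and cholesterol synthesis genes lay inside the random range in all 4 comparisons. Their medians between the GMP genotypes were 0.018, 0.004, 0.10 and 0.003. Xist was the only sex-linked gene above the floor and was high on all 4 arrays, with differences from 0.003 to 0.50, though its probe sets did not share a direction in 3 of the comparisons (as low as -0.53).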

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

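In this part the tests of probe sets that hybridise to several transcripts and of the wild-type GMP array alone were chosen after the result was seen. The other tests were written down before the value they measure was looked at.

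The basophil, mast cell and eosinophil genes lower in knockout GMP formed the first pattern, with 12 genes above the floor. Its median was -1.054, and its place below matched random lists (lower limit -0.38) is the observation that led to the list and tests no explanation. Intensity-dependent scaling would bring the median near 0 under cyclic loess, and it was -0.962. RMA had already made the arrays' distributions alike, so loess could move little. The value speaks only against a trend with intensity left after RMA as the whole cause. What stays open is the Trib1 genotype, a different share of basophil and mast cell progenitors in the sorted gate, and chance between animals or sorts. A feature of the wild-type GMP array, taken up with the third pattern below, stays open too, since there is 1 array per group. A smaller contribution of this lineage to knockout GMP is thus a hypothesis only.

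The macrophage genes lower in knockout MDP formed the second pattern, with a median of -1.56 over 16 resident macrophage genes chosen because they showed it. Loess left the median at -1.65, which again speaks only against a trend with intensity left after RMA. Leaving out probe sets that can hybridise to several transcripts kept 14 members above the floor and left the median at -1.564. Few members rested on such probe sets, so the median could move little. For the 14 kept, the value argues against such probe sets as the cause. RNA of mature macrophages in the wild-type MDP array may explain it: 24 other mature macrophage genes, listed before their values were seen, lay at percentile 0.03 of matched random lists (median -0.28), with Selenop at -1.15 and Fth1 at -0.98. Against a simple admixture stands 1 gene, Apoe, at 4.22 in wild-type MDP and 4.19 in wild-type GMP. In knockout MDP 15 of the 16 resident genes were lower, Apoe among them (-0.33). That count follows largely from how the genes were chosen and weighs on neither side. C1qa was below the floor on all arrays and so decides nothing. The same 24 genes were also low in knockout GMP (median -0.34, percentile 0.6), where 21 of them were above the floor on both arrays. The sort should remove mature macrophages, its gates are not given in the sources used here, and lower expression in knockout MDP themselves stays as open as such RNA.

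The larger number of named genes lower than higher in knockout GMP formed the third pattern. It was not seen in the 5689 probe sets above the floor without a single gene name. Of those, 96 were at least 2-fold higher and 62 lower in knockout GMP. After cyclic loess 89.7% of the genes at least 2-fold apart were lower. Loess moved the median of all genes only from -0.057 to -0.062, since RMA had already made the distributions alike, so it cannot decide on intensity-dependent scaling. The share was 81.6% with no floor and 92.0% with the floor at the 75th percentile, so a dependence on intensity stays open. If the wild-type GMP array alone were unusual, the mitochondrial ribosome, NADH dehydrogenase and proteasome genes would be level between the knockout arrays. Their median was -0.295 there against -0.63 between the GMP genotypes, in between what the explanation and its opposite predict. The prediction assumes that GMP and MDP express these genes alike, which was not tested. A difference between the cell types could give that value with or without an unusual array, so it cannot decide. BioB and BioC read lowest on wild-type GMP, at 10.20 against 10.57 in knockout GMP, 10.85 in wild-type MDP and 10.72 in knockout MDP. The group and the array cannot be told apart with 1 array per group, and the Trib1 genotype stays open. Numbered zinc finger genes, 205 of them, had a median of 0.009 in the same comparison.

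Other results are given as values. In opposite directions in the 2 progenitors, at least 2-fold in each, were 8 genes, a difference that was not tested, and 3 with values raised to the floor, 2 with the mean of probe sets and 0 with 32 added to the linear value. Independent lists would share 0.86 genes higher in GMP and lower in MDP, and 4.04 the other way. Those named by the rule were Aaas (-2.05 in GMP and 1.01 in MDP, or -1.76 and 0.83 once raised), Gdpd3 (-1.22 and 1.78, or -0.78 and 0.40 once raised) and Slc12a3 (1.95 and -1.07). Of 5689 probe sets above the floor without a single gene name, 96 were at least 2-fold higher and 62 lower in knockout GMP, and 74 were higher and 81 lower in knockout MDP. The hybridisation controls BioB and BioC, spiked at low amounts, read 0.37 higher on the knockout than on the wild-type GMP array, while BioD and Cre read 0.036 higher.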

How the results depend on the processing

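No paired analysis was made, because each group has 1 array and the labels carry no replicate numbers. With 1 array per group no array could be left out of its comparison. The alternatives that raise values below the floor to it and that leave out families were chosen after seeing the data. Genes are counted as higher and then lower, for the GMP genotypes, the MDP genotypes, wild-type MDP against GMP and knockout MDP against GMP, and main values were 56 and 368, 128 and 178, 485 and 1445, and 320 and 475, with 12 genes the same way and 8 in opposite ways in both progenitors. Counts that differed by more than 1.5 times follow. At 1.5-fold they were 615 and 1536, 834 and 887, 1850 and 2892, and 1184 and 1480, with 214 the same way and 179 opposite. At 4-fold they were 1 and 6, 0 and 7, 37 and 151, and 44 and 56, with 0 the same way and 0 opposite. With 32 added to the linear value before log2 they were 1 and 15, 0 and 3, 48 and 320, and 62 and 67, with 0 the same way and 0 opposite. These follow from the construction, since a larger size rule or an offset leaves fewer genes. With the floor at the 75th percentile of all values (6925 genes) the counts were 21 and 242 in GMP, 54 and 63 in MDP, 302 higher in wild-type MDP, and 4 opposite. With the mean of all the gene's probe sets they were 24 higher in GMP, 74 and 110 in MDP, 237 higher in wild-type MDP, 200 and 301 in knockout MDP against GMP, and 2 opposite. With no floor 91 were higher in GMP. With values below the floor raised to it they were 29 higher in GMP, 62 and 80 in MDP, 4 the same way and 3 opposite. For the changes of floor, the averaging and the raised values, the cause was not tested. All other counts, among them those without the families (333 lower in GMP, 1354 lower in wild-type MDP), were within 1.5 times of the main count, and the correlation between the 2 genotype differences stayed between -0.0103 and 0.0472. The share of lower genes moved by over 10 points with 32 added (100% in MDP and 87.0% in wild-type MDP against GMP), at 1.5-fold (71.4% in GMP and 61.0% in wild-type MDP against GMP) and at 4-fold (100% in MDP), and by less under loess and centring. Over all alternatives 13 list medians moved by more than the SD between probe sets and 667 did not. That SD is one of single genes and is wide for a median over a list, so few medians could pass it. None of the 35 medians outside the random range turned its direction. Loess and centring left all 35 outside, and 5 moved inside with no floor, 5 with values raised to the floor, 3 with the floor at the 75th percentile, 3 with the mean of probe sets, 3 with 32 added and 2 without the probe sets that can hybridise to several transcripts. At the stricter floor, 28 kept their side, and the lists with fewer than 5 members left gave no value. Among named genes 366 values moved and 2979 did not. Signal over background limits the rest: many of the folds named rest on 1 array's value below the floor.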

Other observations

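Beyond the named genes, the 4 arrays differed in how close the groups lay. Across all probe sets the Pearson correlation was 0.977 between the GMP genotypes and 0.976 between the MDP genotypes, against 0.948 between the wild-type progenitors and 0.967 between the knockout progenitors. It was 0.9497 between wild-type GMP and knockout MDP, and 0.9645 between knockout GMP and wild-type MDP. Wild-type GMP thus lay further from both MDP arrays than knockout GMP did. With 1 array per group this cannot be told apart from an effect of genotype. The actin control probe sets differed between the 3' and 5' ends by 2.01, 1.91, 2.01 and 1.67 (wild-type GMP, knockout GMP, wild-type MDP and knockout MDP), and those of Gapdh by 1.06, 1.20, 1.44 and 1.66. The 2 controls thus do not order the arrays alike in RNA integrity or amplification.

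The heat shock gene Hspa1b stood high in knockout GMP. It read 10.5 there, against 8.76 in wild-type GMP, 7.55 in wild-type MDP and 6.87 in knockout MDP. Dusp1 and Zfp36, of the immediate early and stress list, were lower on that array. In chemokines, Cxcl10 was higher in knockout GMP (1.33, or 0.19 once raised, from a wild-type value below the floor) and Ccl3 lower (-1.17), single probe sets in a list with a median of 0.012.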
